A study of Panax notoginseng with 2 samples.

How the data were processed

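RNA from roots of Panax notoginseng, a medicinal relative of ginseng, was sequenced in 2 Illumina libraries, per the labels' protocols. One library came from plants given 5 µM cadmium, a toxic heavy metal, and the other from untreated control plants. Each group therefore held 1 library, and the labels mention no further replicates. RNA was extracted with TRIzol, per the labels' protocols. The strand specificity of the libraries, the number of reads and the genome build were not given in the sources used here.

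The authors deposited 1 FPKM value (fragments per kilobase of transcript, scaled to library size) per locus and library, for 147111 loci on 32485 scaffolds and contigs. TopHat2 2.0.13, Cufflinks 2.2.1 and Cuffnorm 2.2.1 are listed in the submitters' processing notes, without their settings. The second table gave, for every locus, the position of 1 exon and a Cufflinks class code that compares the transcript listed for it with the reference genes. Here = is called reference structure, j a new splice form of a reference gene, u intergenic, o other exon overlap and x antisense overlap. Another file held exon positions of the first 1694 loci and stopped in the middle of a line. Locus lengths in the table ran from the first to the last base and included introns. The files pair locus identifiers with identifiers of the nearest reference gene, and with no gene name or function. None of the 42 gene lists fixed before the data were examined (metal transport, glutathione, heat shock, ginsenoside synthesis, markers of other cell types and others) could be matched, so 0 lists were tested, and no pathway, cell type or other organism is reported.

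The comparison used log2((cadmium FPKM + 1)/(control FPKM + 1)), a scale that understates the change of low loci. A locus was counted as higher or lower when this ratio was at least 1 or at most -1 and its FPKM was at least 1 in at least 1 library. With 1 library per group there is no replicate check, no p-value was computed, and a difference between the libraries cannot be assigned to the treatment. For classes of loci, the median ratio was placed among the medians of 10000 random lists of the same size, matched on mean FPKM in 20 bins. This percentile describes these 2 libraries. The classes were taken up as groups after the files had been seen.

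Counts were not used here, but the authors' FPKM values of unspliced loci were whole multiples of a step set by locus length and library. The step was fitted on 1-exon reference-structure loci. It corresponded to 19.8 fragments per kilobase and FPKM and 204 bases lost at the locus ends in the control library, and to 11.9 fragments per kilobase and FPKM and 208 bases in the cadmium library. Among 1-exon reference-structure and intergenic loci of 500 bases or more, 98.6% of the values above 0 in the control library and 98.6% in the cadmium library came out as whole fragment numbers within 0.05. These numbers may include a scaling between libraries by the authors' software, so they give how many fragments stand behind 1 FPKM, not the number of reads sequenced. In the exon file, 1282 of 1284 loci taken as 1-exon had 1 transcript of 1 exon. For the 4937 loci with whole numbers in both libraries, ratios were given an exact 95% conditional binomial (Clopper-Pearson) interval. Loci with very high FPKM often missed the tolerance and are left out of that set. For 3 such loci on contig C4800589 the control number was rounded and the same interval given. Such intervals cover counting error only. Fragments without molecular identifiers are not independent molecules. Depth remained unknown for spliced loci.

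The calculations were tested on a simulated data set. It held 28798 loci drawn from the 1-exon reference-structure loci of this comparison, with 100 loci raised 4-fold and 100 lowered 4-fold. The changed loci were picked among the better expressed ones. The size rule called 100% of the raised and 96% of the lowered loci. It also called 3.98% of the unchanged loci that reached 1 FPKM in at least 1 simulated library. Both simulated libraries held counting error only, around 1 shared level, with no spread between plants or preparations. The 3.98% is therefore not the rate of false calls in the real libraries. All simulated fragment numbers in loci of 500 bases or more were recovered (100% in each library). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

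The rule for named loci required an FPKM of at least 10 in 1 library and an informative description. As no locus had a description, its fallback of at most 2 identifiers higher and 2 lower was used, ranked by the log2 ratio. Further loci are given by position and were chosen after their values had been seen, as the extremes of the ratio or of FPKM among loci of 500 bases or more. Positions are 1-based, on the scaffolds and contigs as named in the files. Alternatives were other pseudocounts, filters, scalings, fold thresholds and random lists. Choices on annotation text, on a second expression table and on pathway classes were not run because the files held nothing to apply them to.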

Results

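Transcript levels in roots of Panax notoginseng were compared between 1 library from plants given 5 µM cadmium and 1 library from untreated plants. FPKM was above 0 for 41912 loci in the control library and for 34976 in the cadmium library, and 30123 and 27417 loci reached 1 FPKM. The median of loci at 1 FPKM or more was 9.62 in the control and 9.90 in the cadmium library. One FPKM stood for 19.8 fragments per kilobase in the control library and 11.9 in the cadmium library, a 1.67-fold difference in counting depth. This ratio may include a scaling by the authors' software and is not a ratio of reads sequenced. Of the 147111 loci, 102240 were listed at 0 in both libraries. All differences reported here are between 2 libraries and have no replicate check.

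A few very short intergenic loci held much of the summed FPKM of the control library. Loci under 200 bases made up 48.9% of the summed control FPKM and 17.3% of the summed cadmium FPKM. Of the 20 loci with the highest FPKM, 9 in the control and 6 in the cadmium library were under 200 bases. The highest control value, 470054 FPKM, belonged to a locus of 52 bases, shorter than the 204 bases lost at locus ends, and alone made 20.3% of the control sum. In loci of 500 bases or more the FPKM sums were 1075329 in the control and 1200392 in the cadmium library. The 100 highest of these long loci held 28.7% of the control sum and 38.5% of the cadmium sum.

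The study's comparison asks which root transcripts differ under cadmium. At least 1 FPKM in 1 library was reached by 33904 loci. By the 2-fold size rule 6986 of them (20.6%) were higher in the cadmium library, 9700 (28.6%) were lower, and 17218 were neither. Of the lower loci 4044 were listed at 0 in the cadmium library, and of the higher loci 1328 were listed at 0 in the control. Among the 28532 loci above 0 in both libraries, 5658 were higher and 5656 were lower, with a median log2 ratio of 0.06. Being above 0 in both libraries depends on the change and on depth, and classes that leaned in opposite directions are pooled in these counts. A scaling between the libraries by the authors' software, if made, may also have set this balance.

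Short loci leaned most strongly towards the control library. Of 721 tested loci under 200 bases, 489 were lower and 189 higher in cadmium, and 477 of the lower ones were listed at 0 in the cadmium library. Those above 0 in both libraries had a median log2 ratio of 2.28, towards cadmium. Of 3273 loci of at least 200 and under 500 bases, 1803 were lower and 810 higher. Of 29910 loci of 500 bases or more, 7408 were lower and 5987 higher, with a median log2 ratio of -0.01. Among the 2976 loci reaching 100 FPKM, 38.1% were lower and 31.5% higher.

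Locus classes differed in direction. Reference-structure loci, whose listed transcript matches a reference gene, were mostly lower in the cadmium library. Of 10300 such loci, 5612 were lower (54.5%), 1378 were higher (13.4%), and the median log2 ratio was -1.12. Of the lower ones 3103 were listed at 0 in cadmium. Loci with a new splice form of a reference gene were close to balanced, with 2870 of 14862 higher, 2138 lower and a median of 0.14, which turned to -0.03 when the upper quartiles of the libraries were made equal. Intergenic loci were more often higher, with 2178 of 6223 higher, 1437 lower and a median of 0.42, but the 463 under 200 bases went the other way, with 151 higher, 287 lower and a median of -5.71. Loci overlapping a reference gene on the opposite strand had the highest median of the 5 classes with over 500 loci, 0.55, with 210 of 587 higher and 88 lower. As strandedness was not given, reads of such a locus and of its partner gene cannot be told apart with certainty. Loci with another exon overlap had 341 of 1901 higher and 419 lower.

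The median of reference-structure loci lay below all 10000 random lists matched on expression, whose medians ran mostly from -0.16 to -0.10 (95% range). The medians of new splice forms, intergenic and antisense loci lay above all 10000 lists, and that of other exon overlaps was at percentile 71.1 (18.8 among loci of 500 bases or more). The lists were drawn from all tested loci, so the low reference-structure class pulled them down. The places of the classes are therefore not separate results. Lists this large also spread little (-0.04 to -0.01 for new splice forms), so even a median near 0 can lie outside them. Restricting the comparison to loci of 500 bases or more left the reference-structure median at -0.99, the intergenic median at 0.49 and the antisense median at 0.55. These lengths include introns, so for spliced loci the restriction need not remove short transcripts. Among loci above 0 in both libraries the reference-structure median was -0.52. The class of a locus depended on an assembly of sequencing reads, so the classes are not independent of the levels compared. Reference structure held 119648 of all 147111 loci, and 102240 loci were at 0 in both libraries. Many loci with no FPKM above 0 were therefore in this class.

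**Figure D1:**
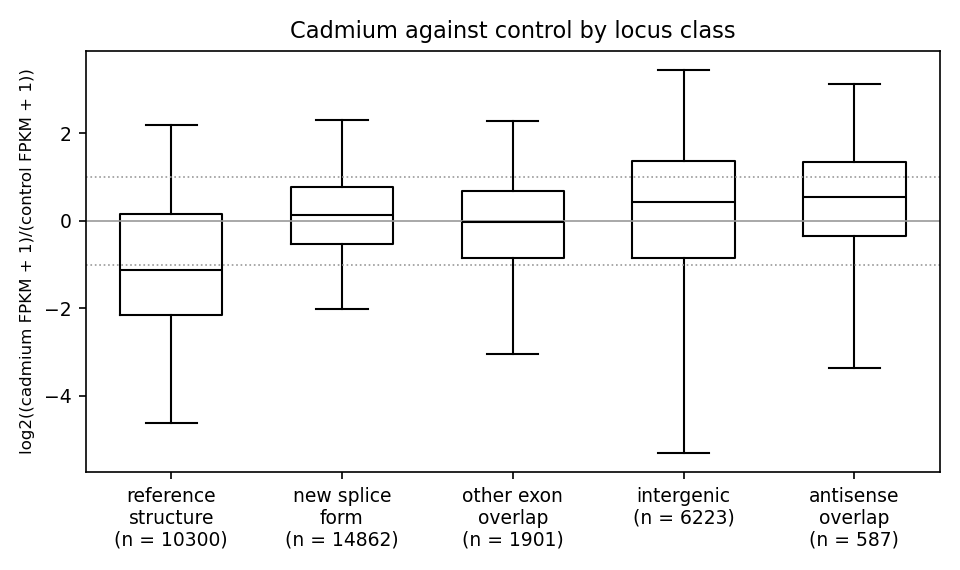
Log2 ratio of cadmium to control FPKM (pseudocount 1) for loci with at least 1 FPKM in 1 library, by locus class; lines mark the median, boxes the quartiles and whiskers the 5th and 95th percentiles, and dotted lines the 2-fold rule. The reference-structure median is at -1.12, while the intergenic and antisense medians are at 0.42 and 0.55.

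Whole fragment numbers in both libraries were found for 4937 unspliced reference-structure and intergenic loci of 500 bases or more, holding 887517 control and 366662 cadmium fragments. By the size rule 665 of them were higher and 1016 lower in cadmium. The counting interval of the ratio excluded equality for 664 and 1011 of these, which the selection of the loci by the same fragments makes nearly certain, so it gives no rate of false calls. The spread between plants was not measured. Reference-structure loci made up 777 of these lower loci and 192 of the higher ones. Intergenic loci made up 239 of the lower and 473 of the higher ones.

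Many loci well covered in one library were listed at 0 in the other. Whether such zeros are absent fragments or failed estimates stays open. Of 1215 unspliced reference-structure loci with at least 29 control fragments, 114 (9.38%, exact 95% interval 7.80 to 11.2) were at 0 in the cadmium library. At the matching depth of 17 cadmium fragments, 17 of 922 such loci (1.84%, interval 1.08 to 2.94) were at 0 in the control library. For intergenic loci the order was the opposite: 40 of 528 (7.58%, interval 5.47 to 10.2) were at 0 in cadmium and 93 of 684 (13.6%, interval 11.1 to 16.4) were at 0 in control. With 1 or 2 control fragments, 77.6% of reference-structure loci and 13.7% of intergenic loci were at 0 in cadmium. With 1 or 2 cadmium fragments, 29.3% and 43.0% were at 0 in the control. With the fragments seen taken as the true level, counting leaves 45.6% and 43.6% at 0 in cadmium. In the control it leaves 13.4% and 11.9%. This ignores the counting error of the 1 or 2 fragments themselves. The expected shares may therefore be too low, and the excesses over them were not tested.

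**Figure D2:**
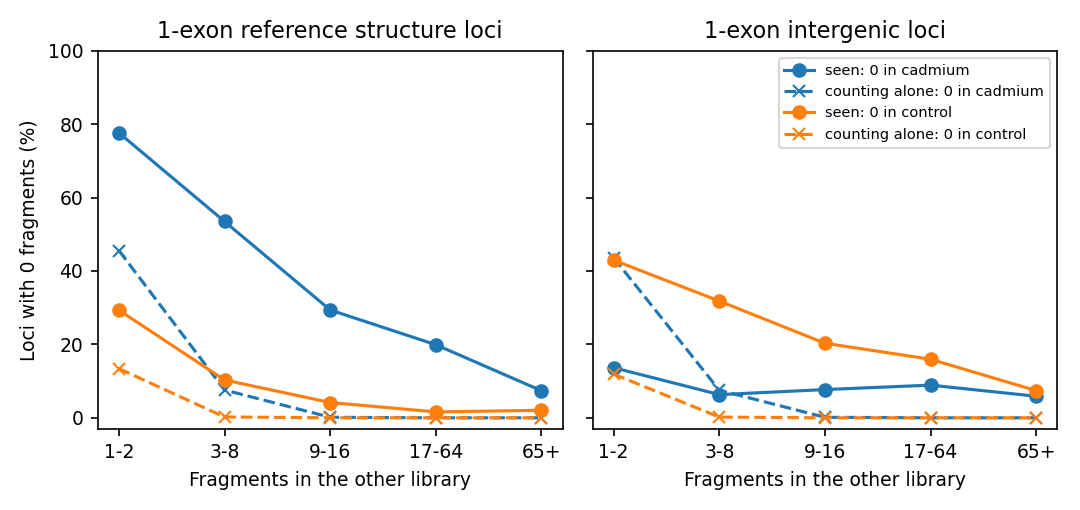
Percent of unspliced loci of 500 bases or more listed at 0 in one library (y axis) by their fragments in the other (x axis), for reference-structure (left) and intergenic loci (right). Solid lines are the loci seen. Dashed lines are what counting gives with the fragments seen taken as the true level, which may be too low at few fragments. At 65 or more control fragments 7.39% of reference-structure loci were at 0 in cadmium, against 2.05% in the reverse direction.

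The extreme ratios by the ranking rule all belonged to short unstranded intergenic loci listed at 0 in 1 library. XLOC_064804 (scaffold20230, 141505 to 141641) was at 15128 FPKM in the cadmium library and listed at 0 in the control. XLOC_026582 (scaffold11356, 22859 to 22989) was at 10075 FPKM in cadmium and listed at 0 in the control. XLOC_022394 (scaffold10483, 26708 to 26759) was at 470054 FPKM in the control and listed at 0 in cadmium. XLOC_001721 (contig C4800589, 1865 to 1975) was at 197822 FPKM in the control and listed at 0 in cadmium. All 4 are shorter than the bases lost at locus ends, so their FPKM rests on a very small effective length.

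Among the 14816 loci of 500 bases or more with at least 1 FPKM in both libraries and 10 in 1, several reference-structure loci changed from low to very high FPKM. The locus on contig C4930213 from 10955 to 24446 stood at 14.3 FPKM in the control and 55194 in the cadmium library, a 3867-fold ratio. A locus on contig C4936261 from 655 to 4669 stood at 5.40 and 6709 FPKM, 1242-fold higher in cadmium. A locus on scaffold5661 from 59835 to 61582 stood at 3.14 and 2582 FPKM, and 1 on scaffold17497 from 16449 to 17237 at 8.02 and 3300 FPKM. In the other direction, the locus on scaffold7194 from 135754 to 137509 stood at 2478 FPKM in the control and 1.58 in cadmium, 1565-fold lower. A locus on contig C4944651 from 18458 to 36871 stood at 2144 and 1.53 FPKM, and 1 on scaffold6751 from 76489 to 78436 at 3002 and 4.19 FPKM. These values have no replicate check, and the fragments behind spliced loci are unknown.

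The most abundant long loci also differed. The highest in cadmium, on scaffold4612 from 99235 to 100118, stood at 56311 FPKM there and at 10630 in the control, a 5.30-fold ratio. A locus on scaffold16557 from 29009 to 31793 stood at 27632 FPKM in cadmium and 558 in the control, 49.5-fold higher. The locus on scaffold22637 from 8512 to 12959 stood at 20622 FPKM in the control and 350 in cadmium, 58.9-fold lower. A locus on scaffold8874 from 190499 to 195441, the highest long locus in the control at 24523 FPKM, was listed at 0 in cadmium. Whether this 0 is an absence of fragments or a failed estimate is unknown. One abundant locus differed little, on scaffold19059 from 44008 to 45125, with 10887 FPKM in the control and 13804 in cadmium.

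One contig was covered almost exclusively in the control library. Its sequence was not used here, so whether it is a transcript of the root, ribosomal RNA or RNA of another source is unknown. All 6 loci on contig C4800589 were intergenic and unstranded, spanned most of positions 1 to 3722, and stood between 3167 and 197822 FPKM in the control. In the cadmium library 3 of them were listed at 0 and the other 3 stood at 1.04, 0.52 and 0.38 FPKM. The 3 loci of 500 bases or more held 11 cadmium fragments and, rounded from the fitted step, 230452 control fragments, 1.16% of the fragments behind the control FPKM scale. Their control numbers were not whole within 0.05, so none of the 3 is among the 4937 loci above. At equal depth the control was 10723-fold higher over positions 1 to 612 (counting interval 4595 to 33026), 6123-fold over 753 to 1281 (interval 1695 to 50562) and 18102-fold over 2226 to 3320 (interval 7070 to 66439).

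**Figure D3:**
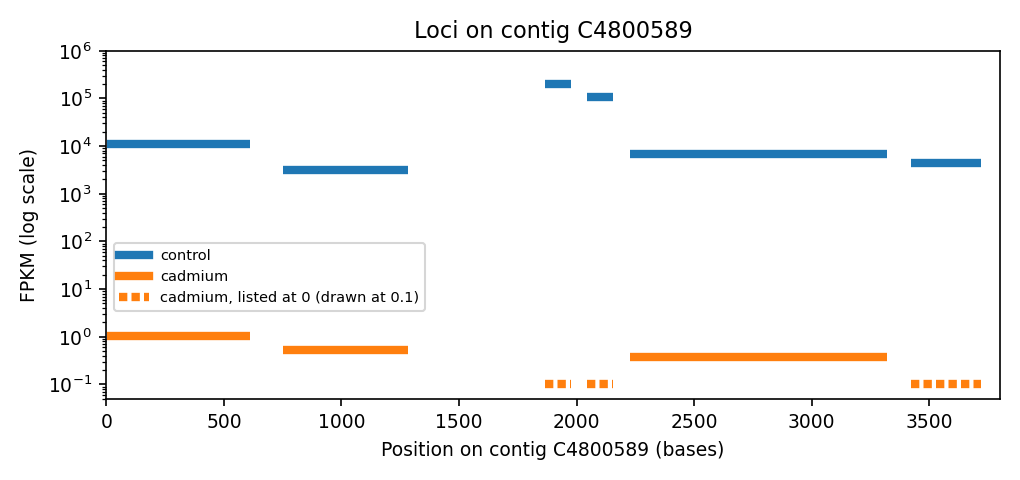
FPKM (y axis, log scale) of the 6 loci on contig C4800589 by position in bases (x axis), each bar spanning its locus, in the control and cadmium libraries; loci listed at 0 are drawn dotted at 0.1. The control bars lie at 3167 FPKM or above and the cadmium bars at 1.04 or below.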

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

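Settings named here were fixed before the data were examined, except the restrictions to loci of 500 bases or more and to loci above 0 in both libraries, which were chosen after seeing the data. No paired analysis was possible because each group held 1 library, and for the same reason no library could be left out. More loci were lower than higher in cadmium under every pseudocount, filter, scaling and fold tried. Among loci above 0 in both libraries this was not so (5658 higher and 5656 lower, against 6986 and 9700). That restriction is partly decided by the change itself and the depth, and a scaling by the authors' software may have set its balance. Counts moved by more than 1.5 times with a pseudocount of 5 (3813 higher, 5329 lower), with a fold of at least 4 (2666 higher, 4784 lower) and, for lower loci, with a minimum of 5 FPKM (6458). Dropping the 1 FPKM filter changed no count, because the size rule with a pseudocount of 1 implies it. The scalings shifted the cadmium library by -0.07 (median ratio set to 0), -0.19 (equal upper quartiles) and 0.13 (sums equal without the 20 highest loci) on the log2 scale. The reference-structure median of -1.12 stayed negative except without a filter, where most loci are at 0 in both libraries and it was 0. It was -1.82 with a pseudocount of 0.1, -0.41 with 5, -1.16 at 5 FPKM, -1.19 with equal upper quartiles, -1.08 without the 20 highest loci, -0.99 in loci of 500 bases or more and -0.52 in loci above 0 in both. The median of new splice forms reversed to -0.032 with equal upper quartiles, a shift of the whole library. It was 0.10 with a pseudocount of 5, 0.082 without a filter, 0.075 with the median ratio set to 0 and 0.26 without the 20 highest loci. The intergenic median stayed positive: 0.53 with a pseudocount of 0.1, 0.21 with 5, 0.26 without a filter, 0.20 at 5 FPKM, 0.36 with the median ratio set to 0, 0.25 with equal upper quartiles, 0.55 without the 20 highest loci and 0.49 in loci of 500 bases or more. The cause of the other moves was not tested. Another 22 values for these counts and medians stayed within their limits. For the 4 loci named by identifier, 8 log2 ratios moved, all with another pseudocount, and none changed direction. The places of the 3 main classes beyond the random lists were kept with unmatched lists and with means, but these places are not separate results.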

Other observations

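All tests in this part were chosen only after the results, or closely related values, were seen. On some scaffolds and contigs most loci differed in the same direction. On contig C4925817, 5 intergenic loci between 17785 and 25848 were all listed at 0 in the control and stood between 1.66 and 3.18 FPKM in the cadmium library. On scaffold17035, all 5 distinct long loci counted between 5886 and 20100 were higher in cadmium, led by a new splice form at 118 FPKM against 2.12 in the control. On scaffold1961, all 5 distinct long loci counted between 12512 and 27529 were lower, and 4 of them were listed at 0 in cadmium. The remaining one stood at 57.5 FPKM in the control and 0.16 in cadmium. Among 1263 scaffolds with at least 5 distinct long loci, 9 had at least 80% of them higher in cadmium, where 1000 shuffles gave 1.84 on average and 6 at most. Several of the 9 hold adjacent unstranded loci that shuffling separates, such as those on contig C4925817. With neighbours up to 1000 bases apart, on the same strand or unstranded, counted once, 3 of 1059 scaffolds remained, within the shuffles (1.57 on average, 6 at most). For lower loci the number was 13, within the shuffles (7.80 on average, 17 at most), and 10 with close neighbours counted once (7.29 on average, 16 at most).

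Reference-structure loci were often at 0 in the cadmium library. Its lower depth is argued against as the whole cause: 162 of 1401 unspliced loci with 17 or more control fragments were at 0 in cadmium. The exact 95% Poisson interval of the number seen was 138 to 189. Counting alone gives 0.0016, with the fragments seen taken as the true level. Loci shorter than the fragments are argued against only as the whole cause. In unspliced loci of 500 bases or more this explanation hardly applies. There 9.38% of well covered control loci were at 0 in cadmium (interval 7.80 to 11.2) and 1.84% the other way (1.08 to 2.94). The explanation stays open for shorter unspliced loci, which were not examined. It also stays open for spliced loci, of which only 5 had a known transcript of 500 bases or more (2 at 0 in cadmium). Zeros that are failed estimates stay open: at 65 or more control fragments 69 loci were at 0 in cadmium and 86 at 1 to 4 fragments (zeros 36.5 to 52.7% of these, 95% interval), while in reverse 10 were at 0 in control and 2 at 1 to 4, and a first version over both classes, with 86 at 0 and 110 at 1 to 4, was undecided too. Assignment of loci to classes also stays open, as does cadmium itself, untested without replicates: over both classes 8.84% of well covered control loci were at 0 in cadmium and 6.85% the other way, with overlapping intervals (7.54 to 10.3 and 5.66 to 8.20). Overlap does not show that the shares are equal. Loci well covered in both libraries also enter both shares.

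Reference-structure loci leaned lower and intergenic loci higher in cadmium. A candidate explanation is that the assembly drew more on the cadmium reads, so that loci with cadmium reads more often received a new structure. It stays open. Of 410 intergenic unspliced loci with 1 or 2 control fragments, 56 were at 0 in cadmium, where counting alone gives 179. Of 461 with 1 or 2 cadmium fragments, 198 were at 0 in the control, where counting gives 54.9. Both expected numbers take the fragments seen as the true level and may be too low, so the size of the excess in the control is uncertain. A rise of these loci would also give fewer zeros in cadmium and more in the control. At equal peak levels the classes differed in the same way, in spliced loci of 2000 bases or more. Among those peaking at 10 to 30 FPKM, new splice forms were 67.1% of loci higher in cadmium and 51.4% of lower ones, and reference structures 11.5% and 30.9%. The reference-structure gap depended on level: 21.5% and 79.5% at 1 to 3 FPKM, but 13.7% and 20.1% at 100 FPKM or more. These differences do not separate the explanations either. A response of these classes to cadmium stays untested with 1 library per group.

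Neighbouring loci moved together beyond class and level. After subtraction of the median of each class and FPKM bin, the log2 ratios of neighbours on the same strand up to 1000 bases apart had Pearson's r = 0.18 and Spearman's rho = 0.16 across 1312 pairs of loci, which are not independent replicates, above the 95% range of r in shuffled neighbours, which ended at 0.053. Pieces of 1 transcript listed as separate loci could give this, and are argued against as the whole cause only weakly. On opposite strands up to 1000 bases apart r was 0.067 (shuffled limit 0.045). As strandedness was not given, reads of such close neighbours cannot be told apart with certainty. Over 5000 and up to 20000 bases apart r was 0.097 on opposite strands (limit 0.050) and 0.056 on the same strand (limit 0.044). Spearman's rho was 0.052, 0.096 and 0.037, the last inside its shuffled limit of 0.045, and over 20000 and up to 100000 bases r was inside the range (0.0054 same strand, 0.044 opposite) but rho on opposite strands was 0.075 (limit 0.065). Shared regulation of neighbours remains a hypothesis, with no replicate to test it.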
